A study of Mus musculus with 4 samples.

How the data were processed

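Ribosome profiling, which sequences the mRNA fragments that ribosomes protect from nuclease digestion, was carried out on whole mouse testes at day 10. The 4 libraries comprised 2 control testis samples and 2 samples from mice in which Eif5 had been deleted in germ cells with a Stra8-Cre transgene (Eif5 cKO). Groups and replicate numbers were read from the sample titles. Nothing in the sources used here says that the 2 samples of a group came from separate animals, so p-values measured only the spread between these samples, which may be technical. Footprints were obtained with a commercial ribosome footprinting kit, per the labels' protocols.

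Bowtie2, STAR and featureCounts and the genome build GRCm38 were named, without versions, in the submitters' processing notes. The settings for multi-mapping and strand are not given in the sources used here, so genes with near-identical copies (histones, globins, ribosomal proteins, tubulins) may share reads. The deposited table listed 14984 genes by symbol, and each of these had at least 10 reads in total over the 4 libraries. Although the deposited columns were named raw counts, their values were not whole numbers, so the unit was taken as a normalized signal. Within each column every value was a whole multiple of the value of 1 read, and whole reads were recovered for 100% of values at a relative tolerance of 1e-06. The divisors were 1.23 and 0.871 for control replicates 1 and 2, and 0.880 and 1.11 for Eif5 cKO replicates 1 and 2. These equalled the median-of-ratios size factors recomputed from the recovered reads. No row lacked a gene name, and 0 columns belonged to other samples.

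Because the deposited signal was not a raw count, the edgeR quasi-likelihood test chosen before the data were examined gave way to limma 3.58.1 (R 4.3.3). limma was fitted with an intensity trend to log2(value + 1), with group as the only term, over genes passing the default filter of edgeR 4.0.16 (filterByExpr, minimum count 10) on the recovered reads. This left 12095 genes. A fold change on this scale understates the change of genes with low values. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. With 2 samples against 2, a permutation of sample labels cannot give a two-sided p below 0.333, so the calls rested on limma's pooling of variance over genes (2 residual and 37.0 prior degrees of freedom).

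A set of 25 gene lists (germ cell stages, somatic cell types, stress responses, DNA repair, translation and metabolism) and the rule for naming genes were fixed before the data were examined. The rule named Eif5, the 6 called genes with the largest log2 fold change in each direction, and the 2 members with the smallest p in each list. The 12 largest changes had to have a mean CPM of at least 10, no overlap between groups and a symbol that was not a predicted or clone name. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. At an estimated correlation camera uses the 2 residual degrees of freedom, so its p-values also reflect the few samples. The share of footprints in each list was the percentage of the library total, given without a test. Gene types and coordinates came from a RefSeq gene table for GRCm38. Of the 14984 symbols, 13941 matched it directly, 682 matched by a synonym and 361 did not match.

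The fits were tested on simulated negative binomial reads with the real means, dispersions and library sizes, of which 11748 genes passed the filter and 200 genes were changed. For the comparison of Eif5 cKO with control, limma recovered 20% of 100 genes changed 2-fold and 73% of 100 genes changed 4-fold, with 1 false call among 94 calls. With no gene changed, limma called 0 genes and camera called 0 lists, and edgeR, DESeq2 and limma-voom also called 0 genes. The simulated genes varied independently, so the 0 list calls do not show how camera behaves where genes of a list vary together. Depth per library was 2225964 to 2934609 recovered reads.

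The alternatives, set before the data were examined unless stated, were DESeq2 size factors in an edgeR fit, upper-quartile factors, library totals, scaling on the Sertoli cell list, DESeq2 1.42.0, limma-voom, no filter, and a stricter filter of 50 reads in 2 libraries. Further alternatives left out abundant, ribosomal protein and mitochondrially encoded genes, left out each library in turn, added a replicate block, or used stricter thresholds. The edgeR test with TMM factors was the test planned first, and its use on the recovered reads was decided after seeing the data. TMM factors in limma, pseudocounts of 0.5 and 4, protein-coding genes only, and list members looked up by older symbols were added after seeing the data. RNA libraries were not analysed here, so no translational efficiency was computed.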

Results

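Ribosome footprints were measured in testes of day 10 mice, when the first germ cells enter meiosis, in 2 control samples and 2 samples with germ-cell deletion of Eif5 (Eif5 cKO). Eif5 encodes eukaryotic translation initiation factor 5, a GTPase-activating protein of the scanning ribosome complex. The comparison asked how footprint levels in the testis differed when Eif5 was deleted in germ cells with Stra8-Cre. Control replicates 1 and 2 held 2934609 and 2225964 recovered reads, and Eif5 cKO replicates 1 and 2 held 2296938 and 2782527. Protein-coding genes took 90.7% to 92.8% of reads in each library. The libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 7.03 between the controls and 9.14 between the Eif5 cKO samples. Separate preparations of the same material could also differ so, and this does not show separate animals. Each library was counted as 1 sample. Eif5 cKO replicate 2 was no further from the controls than from Eif5 cKO replicate 1 by the correlation of log2 values across genes, which was 0.930 and 0.923 with control replicates 1 and 2 and 0.920 with Eif5 cKO replicate 1, against 0.944 between the controls. Its chi-square per degree of freedom was 7.65 against control replicate 2, and above 9.14 against control replicate 1.

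Eif5 itself (chromosome 12, 111538101 to 111546753, GRCm38) had a mean value of 334 ± 42.9 (SD, n = 2) in control and 219 ± 65.7 (SD, n = 2) in Eif5 cKO. The single values were 365 and 304 in control and 173 and 266 in Eif5 cKO, so both knockout samples lay below both controls. Groups did not overlap, in either direction, for 40.8% of the 12095 genes tested, against 33.3% expected by chance. The log2 fold change was -0.63 (SE 0.25, 95% interval -1.14 to -0.13), and limma with Benjamini-Hochberg adjustment gave an adjusted p of 0.319, short of the threshold. Somatic cells, which kept Eif5 by design, were part of the tissue. Germ cells in which the Stra8-Cre transgene had not acted would also have kept Eif5, and their share was not measured here. The deposited value sums the whole gene, so the deleted part could not be read separately.

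Of the 73 genes that fell in Eif5 cKO testes, 23 belonged to the germ cell lists and 30 to any of the gene lists. Prss50, a testis member of the serine protease family, was 12-fold lower, with 256 ± 16.4 in control and 20.4 ± 1.57 in Eif5 cKO (SD, n = 2 each). Its log2 fold change was -3.59 (SE 0.34). The other 5 decreases named by the rule for large changes, which left out genes with predicted or clone names, were those of Ly6k, a germ cell surface protein (log2 fold change -3.67, SE 0.68), Ddb2, a subunit that recognises ultraviolet DNA damage (-3.07, SE 0.67), Ugt8a, a galactolipid-forming transferase (-2.93, SE 0.45), Cpeb1, a binding protein of mRNA polyadenylation elements (-2.79, SE 0.47), and the testis histone gene Hist1h2aa (-2.73, SE 0.26). Among genes that rose, Fam222a had the largest change, from 21.7 ± 14.4 to 86.5 ± 9.41 (SD, n = 2 each; log2 fold change 2.11, SE 0.46). It was followed by Hsd17b1, which converts estrone to estradiol (1.44, SE 0.35), the small nucleolar RNA genes Snord87 and Snord123 (both 1.31, SE 0.27 and 0.30), Mxra7 (1.29, SE 0.29) and Gnas, the stimulatory G protein alpha subunit (1.27, SE 0.31).

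In total, limma with Benjamini-Hochberg adjustment called 82 of 12095 genes, 73 lower and 9 higher in Eif5 cKO. Of the 73 lower genes 72 were protein coding, and the other was the pseudogene Gm371. Of the 9 higher genes 5 were protein coding and 4 were noncoding RNAs, whose reads need not be ribosome footprints. Besides the 6 above these were Drd4 (log2 fold change 1.22), Snord15a (1.15) and the guide RNA gene Gm23751 (1.13), which like Gm371 were chosen after their values were seen. Small nucleolar RNA genes as a class took 0.365% and 0.437% of reads in the control libraries and 0.581% and 0.591% in the Eif5 cKO libraries. Their median log2 fold change was 0.43, and -0.002 with the libraries scaled on the Sertoli list. The edgeR quasi-likelihood test on the recovered reads called 92 genes. Leaving out control replicate 1, control replicate 2, Eif5 cKO replicate 1 or Eif5 cKO replicate 2 changed the total to 10, 20, 127 or 346 calls. Of the 22 named genes that passed, 5, 9, 16 and 21 still passed in these same fits. Without Eif5 cKO replicate 1, the log2 fold changes were -2.0 for Ly6k, -2.0 for Ddb2 and 0.84 for Snord87. Of the higher genes named by the rule for large changes, none passed with the libraries scaled on the Sertoli list. In DESeq2 only Snord87 of these passed. Of the decreases named by the same rule, Ly6k did not pass in DESeq2, and Ddb2 did not pass in limma-voom. Ly6k had 1 and 23 reads in Eif5 cKO replicates 1 and 2.

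**Figure D1:**
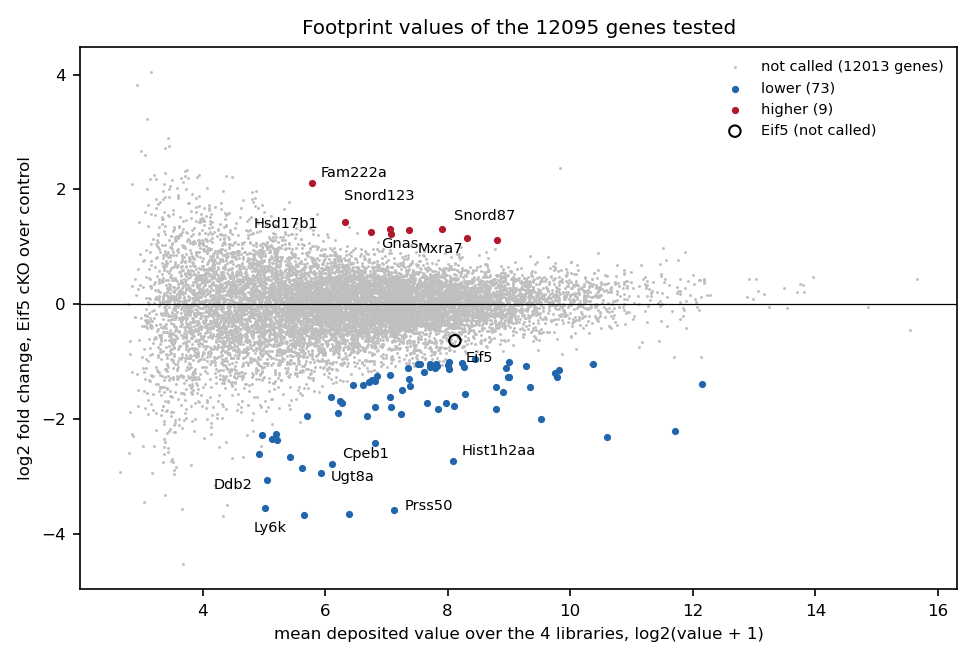
Log2 fold change (Eif5 cKO over control) against the mean deposited value of each gene over the 4 libraries, as log2(value + 1), for 12095 genes. Blue points are the 73 genes called lower, red points the 9 called higher, grey points the rest, and the open circle marks Eif5 at -0.63.

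**Figure D2:**
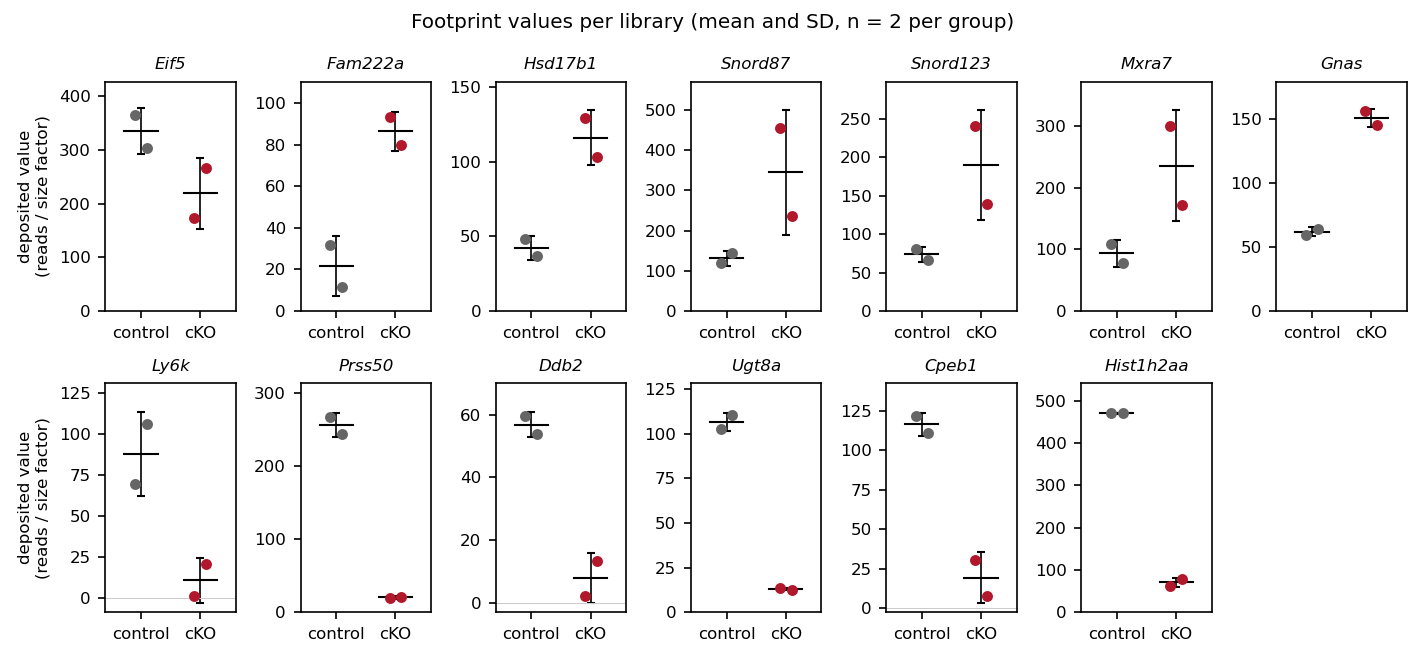
Deposited value (reads divided by the size factor) in each library for Eif5 and the 12 genes named for large called changes, each panel on its own axis. Dots are libraries, horizontal lines are group means and bars are the SD (n = 2 per group); Prss50 fell from 256 to 20.4 and Fam222a rose from 21.7 to 86.5.

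The genes with positions in the RefSeq table lay on many chromosomes. Prss50 is at 110857964 to 110864629 on chromosome 9, Hist1h2aa at 23934437 to 23934913 on chromosome 13 and Ly6k at 74796874 to 74799968 on chromosome 15. Fam222a is at 114568251 to 114613220 on chromosome 5 and Hsd17b1 at 101077968 to 101081188 on chromosome 11.

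The lists of meiotic prophase, pan-germ-cell and differentiating spermatogonia genes were placed below other genes by camera at its preset correlation only, not at an estimated correlation (adjusted p = 0.123, 0.123 and 0.203). The estimated correlations were 0.0118, -0.0281 and -0.0383, near or below the preset 0.01. The lost calls therefore do not show a higher correlation within these lists. All 25 tested genes of meiotic prophase had a negative log2 fold change, with a median of -1.57, and 13 of them fell over all genes tested and 23 when adjusted over the list alone. Sycp1, the transverse filament of the synaptonemal complex, went from 422 ± 59.7 to 126 ± 39.4 (log2 fold change -1.77, SE 0.26), and the meiotic cohesin gene Stag3 from 466 ± 90.4 to 155 ± 10.2 (-1.57, SE 0.24; SD, n = 2 each). The list took 0.188% ± 0.0173 of the control libraries and 0.0674% ± 0.00829 of the Eif5 cKO libraries (SD, n = 2). Rad51ap2 had no reads in Eif5 cKO, and with it set at a bound of 3 reads the median stayed at -1.57. Of 19 genes of the pan-germ-cell and piRNA list, 8 fell over all genes and 12 when adjusted over the list alone, with a median of -0.81. They included Tex101 (-1.99, SE 0.23) and Dpep3 (-1.83, SE 0.26), both germ cell surface proteins. Of 12 genes of differentiating spermatogonia, 2 fell over all genes and 6 when adjusted over the list alone, with a median of -0.71. The 2 were Stra8, which is induced by retinoic acid before meiosis (-1.53, SE 0.24), and the X-linked homeobox gene Rhox13 (-1.78, SE 0.30). At the preset correlation, camera with Benjamini-Hochberg adjustment gave adjusted p = 7.92e-36, 4.41e-19 and 1.19e-08 for these 3 lists. With either control replicate left out, fewer meiotic and pan-germ-cell genes passed over all genes. Without control replicate 1, control replicate 2, Eif5 cKO replicate 1 and Eif5 cKO replicate 2, the meiotic median was -1.39, -1.77, -1.45 and -1.58. The pan-germ-cell median was -0.84, -0.82, -0.79 and -0.83, and that of differentiating spermatogonia -0.72, -0.59, -0.85 and -0.62.

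For undifferentiated and progenitor spermatogonia, 0 of 15 genes passed over all genes or adjusted over the list alone, and the median log2 fold change was -0.19 (camera adjusted p = 0.472). The members with the smallest p were Taf4b (-0.67, SE 0.27) and Rarg (-1.73, SE 0.79), neither of which passed; without Eif5 cKO replicate 2, 1 gene fell. Leaving out control replicate 1, control replicate 2, Eif5 cKO replicate 1 or Eif5 cKO replicate 2 gave medians of 0.03, -0.39, -0.03 and 0.04. Genes of spermatids, cells that are rare or missing at this age, had a median of 0.44 over 6 members with 0 calls over all genes and 0 adjusted over the list alone (camera adjusted p = 0.186). Spaca1 (1.68, SE 1.05), with mean values of 3.60 and 13.3, and Prm2 (0.83, SE 0.73), with 12.4 and 23.4, did not pass. In the same fits the spermatid median was 0.15, 1.31, 0.93 and 0.48, and with the libraries scaled on the Sertoli list camera called the list higher (median 0.12, adjusted p = 0.00984).

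The lists for DNA double-strand break repair and for DNA replication and cell division were placed below other genes by camera at its preset correlation only, and mismatch and excision repair was not. In the list of DNA double-strand break repair, 2 of 35 genes fell over all genes and 4 adjusted over the list alone, with a median of -0.48. These 2 were H2afx, the histone variant phosphorylated at breaks (1246 ± 272 to 513 ± 42.4, SD, n = 2 each; -1.26, SE 0.23), and the checkpoint kinase gene Atr (843 ± 28.7 to 398 ± 43.0; -1.08, SE 0.22). Among DNA replication and cell division genes, 4 of 29 fell over all genes and 9 adjusted over the list alone, with a median of -0.47. Examples were Rrm2, a ribonucleotide reductase subunit (-1.34, SE 0.31), and the helicase subunit Mcm5 (-1.06, SE 0.25); the others were the mitotic genes Cenpe and Bub1, named after their values were seen. camera with Benjamini-Hochberg adjustment gave adjusted p = 8.55e-09 and 5.64e-09 for these lists, and adjusted p = 0.354 and 0.370 with an estimated correlation. edgeR, DESeq2 and limma-voom called 4, 1 and 5 replication and division genes lower. Rrm2 did not pass in DESeq2, and Mcm5 did not pass with the libraries scaled on the Sertoli list. In mismatch and excision repair, Ddb2 was the single gene of 24 that fell, over all genes and adjusted over the list alone. limma-voom called 0 genes of this list, against 1 each by edgeR and DESeq2. The median of that list was -0.20 (camera adjusted p = 0.163), with 10 positive and 14 negative signs, and Parp1 (0.63, SE 0.26) did not pass. With either control replicate left out, fewer genes of each of these lists passed over all genes. Without control replicate 1, control replicate 2, Eif5 cKO replicate 1 and Eif5 cKO replicate 2, the break repair median was -0.36, -0.64, -0.45 and -0.50. The replication median was -0.20 without control replicate 1 and -0.30 without Eif5 cKO replicate 1, and camera called mismatch and excision repair lower without control replicate 2 (adjusted p = 0.0115). The mismatch and excision repair median was 0.01, -0.37, -0.19 and -0.08 in the same order.

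The lists of Sertoli cell, Leydig cell and macrophage markers were placed above other genes by camera at its preset correlation only, not at an estimated correlation (adjusted p = 0.354, 0.223 and 0.439). For macrophages the preset call was also lost without control replicate 1 (adjusted p = 0.125). Of 20 Sertoli cell genes, 1 rose over all genes (Hsd17b1) and 2 adjusted over the list alone (Hsd17b1 and Inha), with a median of 0.38. Inha, an inhibin subunit, had values of 2556 ± 341 in control and 4947 ± 1690.3 in Eif5 cKO (SD, n = 2 each) and did not pass over all genes in limma. In DESeq2 Inha passed and Hsd17b1 did not. Hsd17b1 also did not pass with the libraries scaled on the Sertoli list. The list took 3.21% ± 0.582 of control and 4.24% ± 0.781 of Eif5 cKO libraries (SD, n = 2). Its member Clu alone took 1.49% and 2.06% of reads in control replicates 1 and 2, and 2.71% and 1.94% in Eif5 cKO replicates 1 and 2. This share and the scaling on the Sertoli list, which uses the summed reads, therefore rest largely on Clu. All 9 Leydig cell genes had a positive sign, with a median of 0.72. Of these, 0 passed over all genes and 5 rose adjusted over the list alone (Cyp11a1, Star, Hsd17b3, Cyp17a1 and Insl3, the last 3 named after their values were seen). Cyp11a1, which starts steroid synthesis (0.80, SE 0.24), and the cholesterol transporter Star (0.85, SE 0.29) had the smallest p. Macrophage genes had a median of 0.38 over 14 members, with 0 calls over all genes and 0 adjusted over the list alone; Adgre1 (0.76, SE 0.30) and Mrc1 (0.51, SE 0.23) did not pass. At the preset correlation, camera with Benjamini-Hochberg adjustment gave adjusted p = 1.87e-05, 3.09e-06 and 0.00141 for the Sertoli, Leydig and macrophage lists. Without control replicate 1 the macrophage list had a median of 0.22 and the Sertoli list one of 0.24, and without control replicate 2 the macrophage median was 0.62. Hsd17b1 did not pass without control replicate 1, control replicate 2 or Eif5 cKO replicate 1; without Eif5 cKO replicate 2, 3 Sertoli and 3 Leydig genes rose, and without Eif5 cKO replicate 1, 1 Leydig gene rose.

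For the remaining cell types camera at its preset correlation made no call on the deposited values, and 0 members passed over all genes and 0 adjusted over the list alone in each. The median log2 fold change was -0.19 for 9 peritubular myoid genes (camera adjusted p = 0.441), including Cnn1 (-0.35, SE 0.32) and Myh11 (-0.21, SE 0.23). It was 0.10 for 10 endothelial genes (0.780 by camera), whose mean had the opposite sign (-0.01), including Emcn (-0.76, SE 0.55) and Cldn5 (-0.50, SE 0.42). It was 0.21 for 10 interstitial stroma genes (0.0663 by camera), including Igf1 (0.42, SE 0.23) and Pdgfra (0.37, SE 0.23). For 4 erythroid genes it was 0.51 (0.146 by camera), including Hba-a2 (0.71, SE 0.50) and Hbb-bs (0.39, SE 0.31), which may share reads with near-identical globin copies. camera called the interstitial stroma list higher in the DESeq2 and limma-voom fits on the recovered reads (adjusted p = 0.0122 and 0.0284) and without control replicate 2 (0.00232). With scaling on the Sertoli list its median was -0.24. The erythroid list was called higher without Eif5 cKO replicate 2 (0.0240). Without control replicate 1, control replicate 2, Eif5 cKO replicate 1 and Eif5 cKO replicate 2, the medians were -0.14, -0.13, -0.33 and -0.02 for myoid genes and -0.10, 0.14, -0.17 and 0.37 for endothelial genes. In the same order they were 0.09, 0.34, 0.11 and 0.32 for stroma and 0.74, 0.47, 0.06 and 0.86 for erythroid genes.

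**Figure D3:**
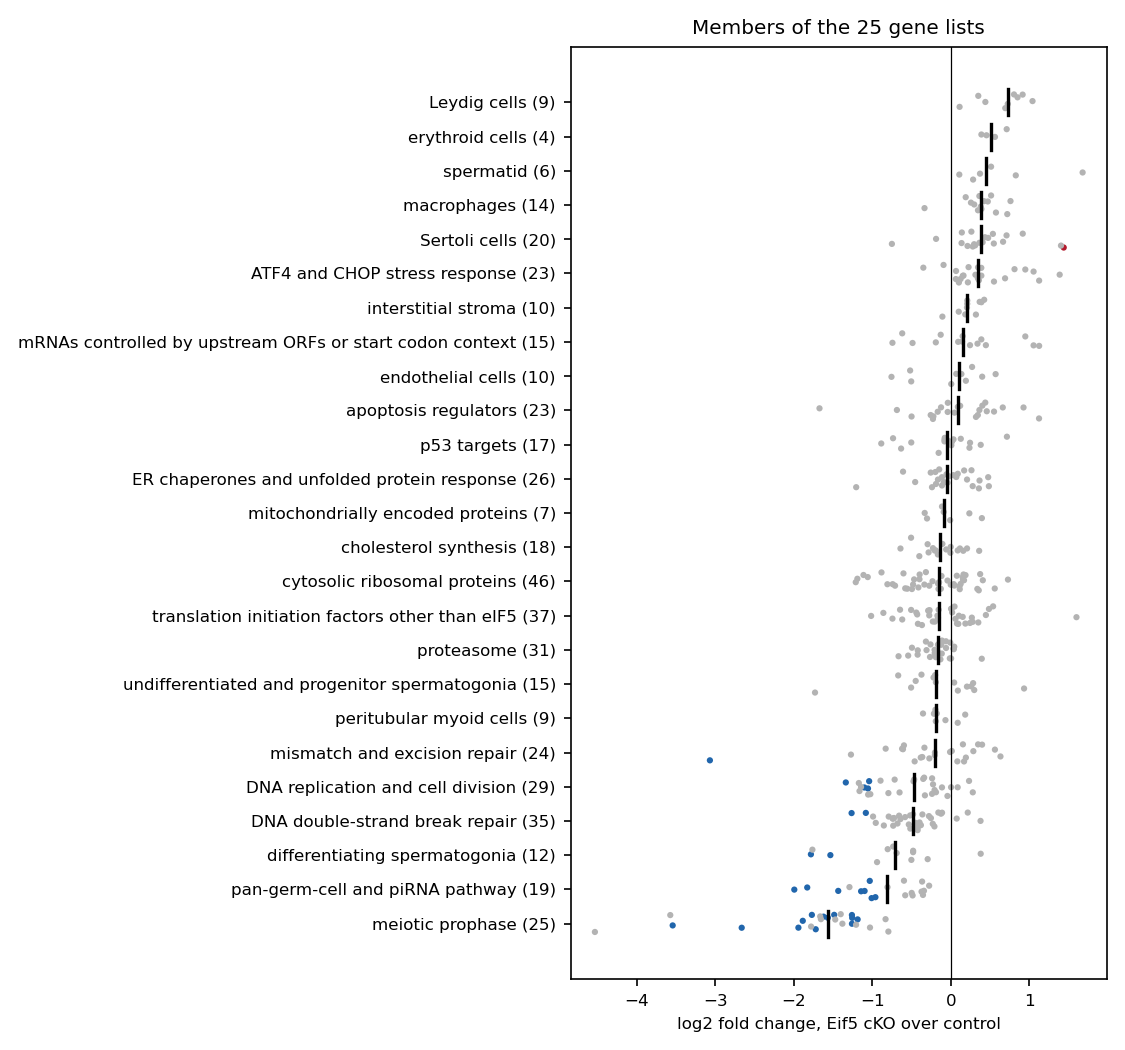
Log2 fold change (Eif5 cKO over control) of each tested member of the 25 gene lists, with the number of members in parentheses and black bars at the list medians. Blue points are members called lower and red points members called higher over all genes tested; the medians run from -1.57 for meiotic prophase to 0.72 for Leydig cells.

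Stress response genes were examined because the study concerned endoplasmic reticulum stress and apoptosis. The ATF4 and CHOP list, targets of the integrated stress response, had a median of 0.34, or -0.10 when libraries were scaled on the Sertoli list, and 21 of its 23 members had a positive sign. None passed singly in limma, with 0 calls over all genes and 0 adjusted over the list alone, and 4 had an unadjusted p under 0.05. Of all 12095 genes tested, 1286 had such a p. Atf4, its central transcription factor, had values of 91.3 ± 29.9 in control and 172 ± 6.09 in Eif5 cKO (SD, n = 2 each; log2 fold change 0.95, SE 0.29), and Ddit3, which encodes CHOP, 23.6 ± 2.47 and 53.1 ± 12.4 (1.12, SE 0.46). camera with Benjamini-Hochberg adjustment placed the list above other genes at adjusted p = 4.02e-04, but at adjusted p = 0.354 with an estimated correlation. In the same libraries the Sertoli, Leydig and macrophage lists also had positive medians.

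ER chaperone and unfolded protein response genes had a median of -0.05 over 26 members (camera adjusted p = 0.780), with 0 calls over all genes and 0 adjusted over the list alone. Sdf2l1 (-1.21, SE 0.49) and Creld2 (-0.61, SE 0.26) did not pass. The p53 targets had a median of -0.04 over 17 members (0.587 by camera), with 0 calls over all genes and 1 lower adjusted over the list alone. That gene, Trp53inp1 (-0.89, SE 0.27), and Bax (-0.50, SE 0.30) had the smallest p in the list. Apoptosis regulators had a median of 0.09 over 23 members (0.441 by camera), with 0 calls over all genes and 1 lower adjusted over the list alone. Bcl2l11, which encodes the proapoptotic protein BIM, was that gene (log2 fold change -1.67, SE 0.46), with an adjusted p over all genes of 0.0824 by limma with Benjamini-Hochberg adjustment, and Bok was at 0.93 (SE 0.35). Without Eif5 cKO replicate 1, 1 gene of the ER list and 1 apoptosis gene fell over all genes, and without Eif5 cKO replicate 2, 1 apoptosis gene rose. Over the fits without 1 library the medians ran from -0.17 to 0.12 for the ER list, from -0.24 to 0.04 for p53 targets and from -0.06 to 0.21 for apoptosis regulators.

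No gene of the translation machinery lists passed over all genes. Initiation factors other than eIF5 had a median of -0.16 over 37 members (camera adjusted p = 0.243), with 0 calls over all genes and 0 adjusted over the list alone; Eif3e (-0.86, SE 0.27) and Bzw1 (-0.74, SE 0.24) did not pass. Cytosolic ribosomal proteins had a median of -0.15 over 46 members (0.0748 by camera), again with 0 calls over all genes and 0 adjusted over the list alone. Rps10 (-0.88, SE 0.34) and Rpl26 (-1.21, SE 0.53) had the smallest p. camera called initiation factors lower without control replicate 2 (adjusted p = 0.0253) and ribosomal proteins lower without Eif5 cKO replicate 1 (0.0428); without Eif5 cKO replicate 2, 1 initiation factor and 3 ribosomal protein genes fell. The mRNAs controlled by upstream open reading frames or start codon context had a median of 0.15 over 15 members (0.320 by camera). Of these, 0 passed over all genes, while 1 rose (Atf4) and 1 fell (Bzw1) adjusted over the list alone. Over the fits without 1 library the medians ran from -0.16 to -0.07 for initiation factors, from -0.29 to -0.07 for ribosomal proteins and from 0.12 to 0.27 for the last list. With scaling on the Sertoli list camera called ribosomal proteins lower (median -0.59, adjusted p = 0.0387).

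Proteasome genes had a median of -0.17 over 31 members, with 0 calls over all genes and 0 adjusted over the list alone, and Psmb2 (-0.54, SE 0.25) and Psmd7 (0.39, SE 0.22) had the smallest p. camera with Benjamini-Hochberg adjustment called the list lower at adjusted p = 0.0489, but gave adjusted p = 0.354 with an estimated correlation. camera gave adjusted p = 0.0782 with the replicate block and 0.0680 in the edgeR fit with TMM factors. The call held in 11 of 20 alternative fits. The camera call was also lost without control replicate 1, Eif5 cKO replicate 1 or Eif5 cKO replicate 2 (adjusted p 0.0938, 0.163 and 0.117). Mitochondrially encoded proteins had a median of -0.09 over 7 members (0.817 by camera) and cholesterol synthesis genes -0.14 over 18 (0.441 by camera), with 0 calls over all genes and 0 adjusted over the list alone in both. Their members with the smallest p were mt-Nd6 (0.39, SE 0.26), mt-Nd1 (-0.33, SE 0.24), Lss (-0.64, SE 0.37) and Stard4 (-0.40, SE 0.27). Over the fits without 1 library their medians ran from -0.19 to 0.05 and from -0.14 to -0.03.

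Across the 25 lists, camera with Benjamini-Hochberg adjustment thus called 10, of which 6 were lower and 4 higher. camera with an estimated correlation called 0 lists (lowest adjusted p = 0.123) and the directional test of fry called 0 (lowest adjusted p = 0.0673), although 4 and 7 lists had an unadjusted p under 0.05. The mixed test of fry, which counts changes in either direction, called the pan-germ-cell and Leydig lists (adjusted p = 0.0143 each), the meiotic and upstream reading frame lists (0.0237 each) and the differentiating and ATF4 and CHOP lists (0.0420 each). In the 18 lists with 0 calls over all genes, 33 of 320 members counted list by list had an unadjusted p under 0.05 in limma. Over all 12095 genes tested 1286 did, a like share. In these 18 lists edgeR, DESeq2 and limma-voom also called 0. Scaling the libraries on the Sertoli list, which by construction brings that list near 0, moved the median of all genes from 0.003 to -0.43. The Sertoli, macrophage and ATF4 and CHOP lists, with medians then of -0.06, -0.05 and -0.10, were still placed above other genes by camera (adjusted p = 0.00172, 0.00637 and 0.00305), the opposite sign to their medians.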

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

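The limma fit with TMM factors, the 2 other pseudocounts, the protein-coding setting and the older symbols were chosen after the data were seen. So was the use of the planned edgeR test with TMM factors on the recovered reads. Called genes were mostly lower in each setting, from 70.5% without Eif5 cKO replicate 2 to 98.8% with scaling on the Sertoli list. The total lay between 56 (DESeq2) and 113 (library totals) when all libraries were used and the threshold kept. It was 37 at adjusted p under 0.01, with 1 higher and 36 lower. Higher calls numbered 14 with library totals, 1 with Sertoli scaling and 19 with limma-voom; the cause was not tested. Leaving out 1 library, where the lone sample is assumed to vary like the other group, gave 10 to 346 calls, 1 to 102 higher and 9 to 244 lower. Of the 82 genes, 9, 19, 48 and 77 were kept without control replicate 1, control replicate 2, Eif5 cKO replicate 1 and Eif5 cKO replicate 2. Adding the replicate block gave 100 calls, 14 of them higher, and kept all 82 genes. Deviations of same-numbered samples correlated at -0.0465 across genes, so the numbers were not taken as pairs.

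Eif5 stayed lower and short of the threshold in 19 of 19 settings (log2 fold change -1.08 to -0.33, adjusted p 0.0506 to 0.912). camera called 8 to 13 lists without 1 library, 0 with an estimated correlation and 0 were called by the directional fry test. Over the other fits and lists, 478 of 497 list results kept their side of the threshold, 10 lost the call (9 for the proteasome, 1 for macrophages) and 9 gained one. The list median changed sign in 26 of the 497, of which 23 were not called. The other 3, with scaling on the Sertoli list, were the Sertoli, macrophage and ATF4 and CHOP lists (medians -0.06, -0.05 and -0.10), which camera still placed above other genes. The meiotic, pan-germ-cell and differentiating lists were called in 20 of 20 fits. Of 1087 results for named genes, 52 lost a call and 13 gained one; 9 fold changes changed sign, all without a call in either fit. All 148 ratios of list shares moved by less than the replicate spread. With 2 libraries per group, leaving 1 out moves a group mean by less than that spread almost by construction. The ratios without 1 library therefore do not show stability. At this depth, a 2-fold change was recovered for 20% of simulated genes.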

Other observations

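The gene choices in this part, the tests of gene classes, the permutation and bootstrap tests and the count of camera calls used against a single library were chosen after the values had been seen; camera, fry and the fits without 1 library were planned. Histone genes stood out among the genes that fell. Of 55 tested genes of the histone clusters, 9 fell and 0 rose (16.4%, against 0.532% of 12040 other genes; Fisher's exact test, two-sided, adjusted p = 9.77e-11 over 3 gene classes), and 42 had a negative sign. Hist1h1a, a linker histone abundant in spermatogonia, went from 6597 ± 124 to 2513 ± 39.1, and the testis variant Hist1h2ba from 2579 ± 424 to 513 ± 31.7 (SD, n = 2 each; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00201 and 6.39e-09). Gm12260, whose RefSeq symbol is H3f4 and which encodes a testis histone H3 (chromosome 11, 58961711 to 58962273), went from 5530 ± 38.1 to 1198 ± 32.8 (adjusted p = 1.14e-07). The median of the 55 genes was -0.50, negative under every scaling tried, and between -0.61 and -0.23 without 1 library; without control replicate 1 or control replicate 2, 3 of these genes were called, without Eif5 cKO replicate 1, 6, and without Eif5 cKO replicate 2, 13 and 1 higher. How reads matching several histone copies were counted is not known here, so single values are uncertain. The Fisher tests of gene classes treat genes as independent, and the classes were picked after the calls were seen, so their p-values are descriptive only.

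X-linked genes made up 11 of the 73 lower calls (2.31% of 476 tested, against 0.534% of 11619 others; Fisher's exact test, two-sided, adjusted p = 1.22e-04), while the median of X-linked genes was 0.04, and -0.008 with library totals or -0.40 with scaling on the Sertoli list. They included the germ cell genes Fmr1nb, Rhox13, Tex11 and Taf7l. Without control replicate 1, control replicate 2, Eif5 cKO replicate 1 and Eif5 cKO replicate 2, there were 1, 5, 17 and 27 lower X-linked calls, and 3 higher ones without the last. Meioc, a partner of Ythdc2 in meiotic entry that the table lists as Gm1564 and that therefore lay outside the meiotic list, fell by 3.66 on the log2 scale (SE 0.47, limma with Benjamini-Hochberg adjustment, adjusted p = 3.19e-06). Shoc1, a meiotic crossover gene listed as AI481877, fell by 2.85 (SE 0.50). Of 72 small nucleolar RNA genes, 57 had a positive sign (median 0.43) and 3 rose, Snord87, Snord123 and Snord15a; under scaling on the Sertoli list the median was -0.002 against -0.43 for all genes, with 0 calls. Without control replicate 1, 0 of them rose, without control replicate 2, 2 did, and without Eif5 cKO replicate 2, 7 did and 1 fell. Without Eif5 cKO replicate 1, 3 rose and 1 fell.

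The first pattern weighed was the lower level of germ cell lists, called by camera at its preset correlation only. A scaling error between libraries moves all genes alike, so it cannot account for differences between the 4 germ cell lists other than spermatid. Their medians spread over 1.38 (100000 permutations of membership, p = 7e-05, and 1.37 to 1.62 without 1 library). That spread does not show whether scaling made the lists negative. Over 20 alternative fits, the highest medians of the meiotic, pan-germ-cell and differentiating lists were -1.39, -0.79 and -0.59. If both lists were read from germ cells alone, an equal loss of every stage would lower the meiotic and pan-germ-cell lists alike. Their medians differed by -0.76 (100000 permutations of membership, p = 8e-05, and -0.94 to -0.56 without 1 library). The meiotic median minus that of the undifferentiated list was -1.38 (100000 permutations of membership, p = 5e-05). The medians had been seen before, the permutations treat genes as independent, and reads from other cells could damp any of these lists. These differences therefore argue against an equal loss for the genes of these lists, but do not exclude it. A shortage of cells entering meiosis was not tested, and fewer ribosomes per mRNA cannot be told apart from less mRNA because 0 RNA libraries were used here. The effect of the knockout on cells and on translation both stay open.

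The second pattern was the higher level of the Sertoli, Leydig and macrophage lists, called by camera at its preset correlation only. If a lower germ cell share raised every other cell type alike, the medians of 6 somatic lists would lie close together. They spread over 0.92 (100000 permutations of membership, p = 4e-05, and 0.62 to 0.86 without 1 library), with myoid genes lowest and Leydig genes highest. The permutations treat genes as independent, while the estimated correlation ran from -0.02 for Leydig to 0.44 for myoid genes. The medians had also been seen before, so this p-value cannot exclude a lower germ cell share as the cause. A scaling error moves all genes alike and cannot account for the spread between lists. The spread does not show whether scaling made the Sertoli, Leydig and macrophage medians positive. With the libraries scaled on the Sertoli list, the Sertoli, macrophage and Leydig medians were -0.06, -0.05 and 0.28, against -0.43 for all genes. An offset common to these lists stays open. A change in the cells of these types, or in their ribosome loading, stays open and may add to a lower germ cell share.

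The third pattern was the higher ATF4 and CHOP list. One library did not carry it, since camera called the list in 4 of 4 fits that left out 1 library (median 0.28 to 0.40). These calls were made at the preset correlation, and the list did not pass with an estimated correlation (adjusted p = 0.354) or in the directional test of fry (0.181). A higher share of Sertoli, Leydig and macrophage cells may contribute: the list median minus the pooled median of those lists was -0.078 (95% bootstrap interval over genes -0.31 to 0.05). These cannot be told apart here, because the interval includes 0, whole testis was measured, and the tests treat genes as independent, which they are not.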
